A study of Mus musculus with 4 samples.

How the data were processed

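Gene expression in single cells was measured in 4 libraries of mouse tumour cells, 1 for each of 2 cell lines (344SQ parental and 344SQ_PD1R1 (140P), called PD1R1 from here on) at each of 2 time points (4 and 6 weeks). Per the labels' protocols, tumours were minced, digested with collagenase, hyaluronidase and DNase, stained with Sytox Blue, sorted for viable cells and run on the 10x Genomics platform. The deposited matrices hold whole-number UMI counts per gene and droplet, with no normalization. The authors made these counts with Cell Ranger on mm10, per the submitters' processing notes, and the file headers give version 5.0.0 for PD1R1 at 4 weeks and 4.0.0 for PD1R1 at 6 weeks and parental at 6 weeks, while that of parental at 4 weeks names Cell Ranger 4. The gene annotation version and the cell-calling settings were not given in the sources used here. Each matrix lists 32285 genes, of which 32158 identifiers were found in GENCODE vM21, used here for gene positions, and 0 symbols begin with Mir29.

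The matrices hold 5506, 9219, 737280 and 11380 droplets for PD1R1 at 4 weeks, PD1R1 at 6 weeks, parental at 4 weeks and parental at 6 weeks. The matrix of parental at 4 weeks thus also holds empty droplets, whereas its barcode list has 5851 entries, so barcodes could not be matched to columns and cells were taken there as droplets with at least 500 UMIs (6135). The total UMI counts were 36017933, 60889504, 62943068 and 71940701. Droplets with at least 500 UMIs, 300 detected genes and less than 20% mitochondrial UMIs were kept. Mitochondrial UMIs removed 324, 2327, 575 and 1122 droplets. Doublet scores were computed per library with Scrublet in scanpy 1.11.5, given an expected rate of 6%. Its automatic threshold marked 0, 0, 1 and 0 cells and had not worked, so the cells with the highest scores were removed at a rate of 0.8% per 1000 cells, which took 213, 373, 231 and 801 cells (4.13%, 5.46%, 4.30% and 8.00%). Free RNA was not subtracted. Its effect was examined by restricting malignant-like cells to those with no UMI of 7 genes of other cell types (Ptprc, Lyz2, C1qa, S100a8, Cd3e, Pecam1 and Dcn).

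Cells of all libraries were clustered together on log-normalized counts of 2000 variable genes with 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, anndata 0.12.19, scikit-learn 1.9.0), without integration. Clusters were named from markers of 15 classes fixed in advance, as the class with the highest mean log2 fold of its markers over the median of all clusters, with a prior of 10 CPM. A named class needed at least 3 markers detected in 10% of the cluster's cells and a score of at least 0.5. A cluster stayed unnamed if more markers of another class than of its own were among its top 10 genes by fold (of genes detected in at least 25% of its cells), or if its UMIs were low and none of its own markers were there. T-cell and NK-cell clusters were joined as T or NK. The unnamed clusters c3 (269, 27, 7 and 15 cells), c8 with plasma-cell and B-cell genes (73, 22, 4 and 32) and c26 (1, 12, 2 and 25), which was set apart after its leading gene Wfdc18 was seen, entered no class. They made up 343, 61, 13 and 72 cells. Mast or basophil-like cells numbered 5, 0, 3 and 0 and were not compared. All names are rebuilt here and are not the authors' annotation.

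UMI counts were summed per library and class and tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F tests with TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05. PD1R1 was compared with parental over all 4 libraries, and 6 weeks with 4 weeks with line as a term. Classes with at least 30 cells in each library were tested, which left out B-like cells (14 in parental at 4 weeks), fibroblast-like cells (5 in PD1R1 and 27 in parental at 4 weeks) with their lists, and mast or basophil-like cells. Of 35 gene lists fixed in advance, 25 were run in malignant-like cells, and interferon, MHC and cell-state lists in their classes. Camera in limma 3.58.1 tested each list on log2 CPM with voom weights, at a preset correlation of 0.01 and then with an estimated correlation, with Benjamini-Hochberg adjustment within the class. Fry tested whether a list's genes change in either direction, without comparing them with other genes. Adjusted p-values of list tests in the text are camera's unless fry is named. Errors of log2 differences are standard errors of the edgeR fit, and CPM (UMIs per 1000000 UMIs) are scaled by TMM factors for genes named by rule and unscaled elsewhere. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. A fold against a line with no UMI was computed against a limit of 3 UMIs over the line, and counting intervals of ratios are exact.

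The genes named were chosen by a rule. In malignant-like cells it took the 12 with the largest rise and the 12 with the largest fall among those past the threshold, in the same direction at both times and with a mean of at least 20 CPM in the higher line. Where fewer passed, places were filled by the largest differences with no overlap between lines. Ribosomal, mitochondrial, hemoglobin, Gm-number, Rik, Xist and Y-linked genes were left out. The rule took 5 and 5 in other comparisons, the 2 to 4 members of each list with the smallest p, and 10 genes always. The 8 genes called in cluster c12 are all named, 5830405F06Rik outside the rule, as are Cdkn2b and the Y-linked genes, chosen after their values were seen. Groups, tests, markers, lists, this rule and most alternatives were set before the data were examined. The exceptions are the droplet choice for parental at 4 weeks, the doublet removal, the marker scoring and the alternatives given as added later.

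Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, the time point as a block, leaving out each library, keeping doublets, a stricter filter (1000 UMIs, 500 genes, 10% mitochondrial), Leiden resolution 2, cells with no UMI of other cell types, thinning to 5000 UMIs with 865 malignant-like cells per library, and thinning to 1000 UMIs before clustering. RLE factors moved the median log2 difference over all genes by at most 0.0105 in size. The 4-week and 6-week counts of a line differed by more than sampling noise (chi-square per degree of freedom 53.7 in PD1R1 and 129 in parental malignant-like cells).

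The tests were tried on simulated data in 5 draws, with 200 genes changed by 50 per fold size and the spread of the real libraries. For the lines in malignant-like cells (14346 genes), edgeR recovered 0.0% of 2-fold, 3.2% of 4-fold, 36.4% of 8-fold and 62.0% of 16-fold changes and called 9 of 70730 unchanged genes. DESeq2 recovered 22.0%, 84.8%, 95.2% and 97.2% (55, 212, 238 and 243 of 250 genes) with 786 unchanged genes called. In these draws its false calls thus outnumbered its true ones. That balance depends on how many genes were changed and does not carry over to the real data. For the weeks edgeR recovered 0.0% at every fold. There DESeq2 called 54, 220, 241 and 247 of 250 changed genes per fold and 786 unchanged ones. In T or NK-like cells (11447 genes) edgeR recovered 0.8%, 30.4%, 84.8% and 96.0%. A list shifted 2-fold was called in 5 of 5 draws with the preset correlation and in 0 of 5 with an estimated one, and 0 of 120 unchanged lists were called. With a low spread (biological coefficient of variation 0.1) the estimated one called it in 4 of 5. Simulated genes were drawn independently, so these draws cannot show how often the preset correlation falsely calls lists of correlated genes. In the real data estimated correlations ranged up to 0.75 (interferon-gamma genes in neutrophil-like cells). Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.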

Results

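Single-cell RNA sequencing by the droplet method of 10x Genomics was used to profile tumours grown in mice from 2 related lung cancer models with mutant Kras and Trp53. The 344SQ line is the parental model, and 344SQ_PD1R1 (140P), called PD1R1 from here on, is a derivative obtained after tumours stopped responding to an antibody against PD-1, an inhibitory receptor of T cells. All mice received a control IgG antibody each week. The data comprised 4 libraries, 1 per line at 4 weeks and 1 per line at 6 weeks of growth, so each line had 2 libraries. Live cells had been sorted with a viability dye, with no selection for a cell type per the labels. After filtering, 4948 cells were analysed from PD1R1 at 4 weeks, 6459 from PD1R1 at 6 weeks, 5144 from parental at 4 weeks and 9207 from parental at 6 weeks. These cells held 33569770, 51592060, 50744192 and 61716830 unique molecular identifiers (UMIs), with medians of 2908, 3515, 5780 and 2665 per cell. In the paragraphs that follow, 4 values in a row are given in that order. The labels do not say that the libraries came from separate animals, so p-values of single genes measure the spread between these libraries. That spread also includes the 2 time points. Camera's p-values at the preset correlation instead compare a list's genes with the other genes, taken as nearly independent. Small values there are not evidence that a difference is replicated between libraries.

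Malignant-like, T or NK-like, B-like, neutrophil-like and macrophage or monocyte-like cells made up most of each library. Neutrophil-like cells were 2.39% and 6.80% of cells in the PD1R1 libraries and 21.8% and 18.5% in the parental ones, a mean of 4.59% ± 3.12 (SD, n = 2) against 20.1% ± 2.27 (SD, n = 2). With a stricter cell filter these shares were 1.43%, 4.18%, 11.8% and 10.9%, and the difference between lines was -8.58 percentage points in place of -15.6. T or NK-like cells were 35.0%, 37.4%, 13.8% and 30.1% of cells, a mean of 36.2% ± 1.73 (SD, n = 2) in PD1R1 and 21.97% ± 11.52 (SD, n = 2) in parental tumours. B-like cells were 28.1%, 18.2%, 0.272% and 18.1%, and the parental 4-week library held only 14 of them (exact 95% interval 0.149% to 0.456%). Malignant-like cells were 19.97%, 27.8%, 53.2% and 22.7%, so the difference between lines was -33.2 percentage points at 4 weeks and 5.05 at 6 weeks. Macrophage or monocyte-like cells were 5.98%, 5.57%, 8.98% and 6.32%. With a library left out the difference between lines in the malignant-like share, -14.1 percentage points over all 4, was 1.14 without the parental 4-week and -29.3 without the parental 6-week library. In the same order it was 6.08 and 22.4 for T or NK-like cells (14.2 over all 4), 5.05 and 22.8 for B-like cells (13.9) and -0.543 and -3.20 for macrophage or monocyte-like cells (-1.87), and without the PD1R1 4-week library it was 8.99 for B-like cells. Fibroblast-like cells numbered 5, 47, 27 and 77, and no cluster carried endothelial markers as its leading class. With 2 libraries against 2 the smallest two-sided exact permutation p is 0.333, so such a test of shares could not reach 0.05. Tissue digestion, the viability sort and the mitochondrial filter, which removed 5.88%, 25.2%, 9.37% and 9.86% of droplets, can each set the shares.

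**Figure D1:**
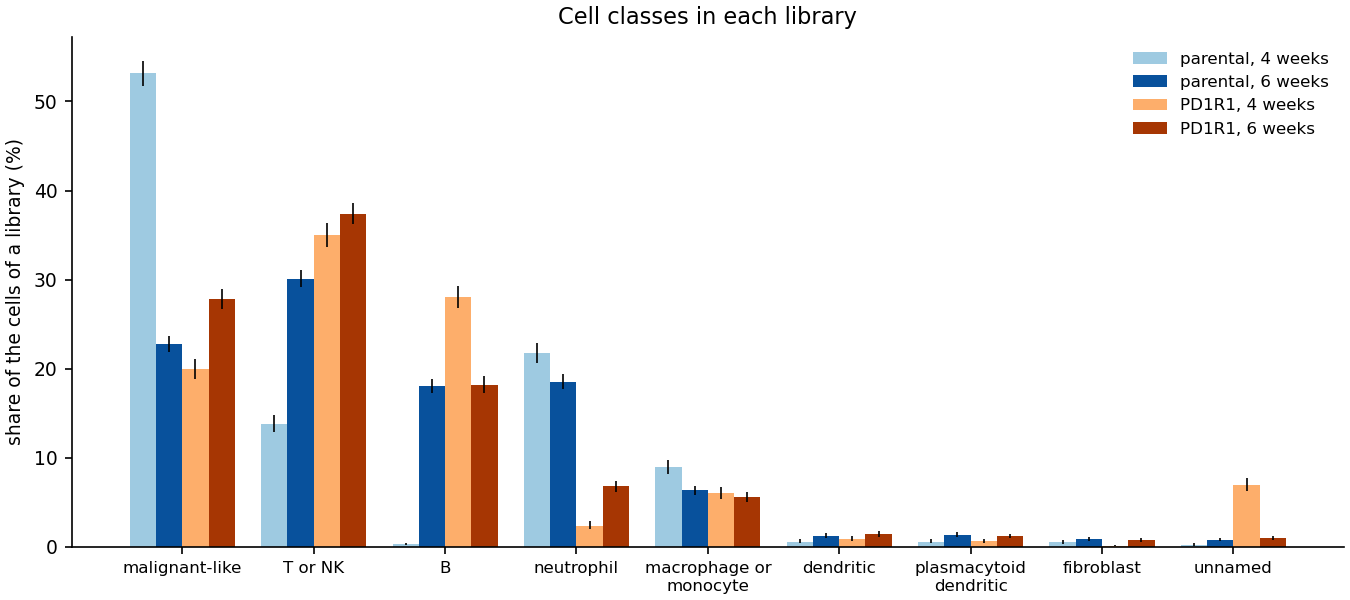
Percentage of analysed cells in each cell class (horizontal axis, named by marker genes) for each of the 4 libraries, with exact 95% intervals that cover counting error only. Neutrophil-like bars stand at 21.8% and 18.5% in the parental libraries and at 2.39% and 6.80% in the PD1R1 libraries, and the B-like bar of the parental 4-week library is at 0.272%.

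The series asks which genes differ between the models in the malignant compartment. Cdkn2a encodes the cell-cycle and p53-pathway regulators p16Ink4a and p19Arf. In malignant-like cells it was at 16.6 and 8.64 CPM (UMIs per 1000000 UMIs of the class in the library) in PD1R1 and at 575 and 607 in parental tumours, a log2 difference of -5.56 ± 0.39 (SE, n = 2 per line). Its neighbour Mtap, an enzyme of methionine salvage, went the other way, with 434 and 249 against 45.3 and 53.8 (log2 difference 2.78 ± 0.32). The claudin gene Cldn7 was at 0.96 and 3.25 against 69.3 and 140, and Cldn4 at 2.29 and 2.97 against 29.4 and 79.3. S100a4, a calcium-binding protein of motile and mesenchymal cells, stood at 898 and 593 against 93.1 and 205. None of these differences passed edgeR's quasi-likelihood test over all genes: 0 of 14346 genes did, with 1450 at an unadjusted p under 0.05 and a smallest adjusted p of 0.151 (the epithelial transcription factor Ehf), whereas DESeq2 called 468 (127 higher and 341 lower in PD1R1). In 5 simulated draws of this comparison DESeq2 called 786 of 70730 unchanged genes, more than the changed genes it called. Few genes were changed there by design, so this balance does not carry over to the 468. How many of the 468 are false is not known. The adjusted p of Cdkn2a was 0.151 by edgeR and 2.5e-60 by DESeq2, and that of Mtap 0.158 and 1.1e-15. By chance the 2 lines do not overlap for 33.3% of genes. In the classes described below this share was 32.2% in T or NK-like, 32.8% in macrophage or monocyte-like and 36.5% in neutrophil-like cells. Dendritic-like cells gave 30.4%, plasmacytoid dendritic-like cells 24.4%, T-cell cluster c12 24.5% and malignant-like cluster c5 43.6%. Over all malignant-like cells the lines did not overlap for 5992 genes, 41.8% of those tested. The edgeR count was 87 without the parental 4-week library and 510 without the parental 6-week library, each leaving a line with a single library assumed to vary like the other.

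The remaining genes with the widest gaps between lines are given as values, since none passed edgeR's test. Higher in both PD1R1 libraries were Ambp, the precursor of bikunin (37.1 and 59.7 against 3.05 and 3.90, log2 difference 3.80 ± 0.31, adjusted p 0.151 by edgeR and 5.0e-25 by DESeq2), and the airway mucin Muc5b (42.2 and 73.9 against 6.32 and 12.1). The interferon-induced membrane protein genes Ifitm1 (log2 difference 2.31 ± 0.35) and Ifitm3 (2.22 ± 0.52) are close paralogs whose reads may be shared. Gpx8 (2.11 ± 0.28), Filip1l (1.94 ± 0.48), the collagen VI chain Col6a2 (1.82 ± 0.36), the basal keratin Krt14 (2.00 ± 0.58) and the morphogen Bmp7 (3.15 ± 1.43; 32.2 and 15.3 CPM against 0.09 and 5.30) completed the group. The immunoglobulin gene Igkv6-15, a member of a family of similar genes, was at 131 CPM in the PD1R1 6-week library and at 1.78, 0.34 and 1.12 in the others, and the antibody light chain Igkc was at 10.3, 70.8, 2.25 and 142 in malignant-like cells. Igkc is among the 10 leading genes of the B-like cluster c1 and the unnamed cluster c8, so transcripts of other cells can enter its values. Lower in both PD1R1 libraries were the surfactant gene Sftpb (0.36 and 0.27 against 842 and 20.7), the glutathione peroxidase Gpx2 (0.10 and 0.14 against 44.6 and 14.2) and Eva1a (0.10 and 0.10 against 43.6 and 3.59). Over both libraries Gpx2 had 6 UMIs in PD1R1, a ratio of 263 with a counting interval of 121 to 718, and Eva1a 5 UMIs, a ratio of 261 with an interval of 112 to 804. These ratios were 119 and 36.0 without the parental 4-week library. Sftpb leads cluster c6, which held 39.4% of parental 4-week malignant-like cells and 1.52%, 1.23% and 3.82% in PD1R1 at 4 and 6 weeks and parental at 6 weeks. Ly6k (-4.45 ± 0.44), Cmtm8 (-4.98 ± 0.54), Tmc4 (-4.43 ± 0.52), Spink4 (-5.02 ± 0.72), AU021092 (-5.81 ± 1.59) and Igfbp5 (-4.42 ± 1.35) were the others. AU021092 was at 0.81 and 0.17 against 47.8 and 3.45, and Igfbp5 at 0 and 2.77 against 49.2 and 14.4.

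**Figure D2:**
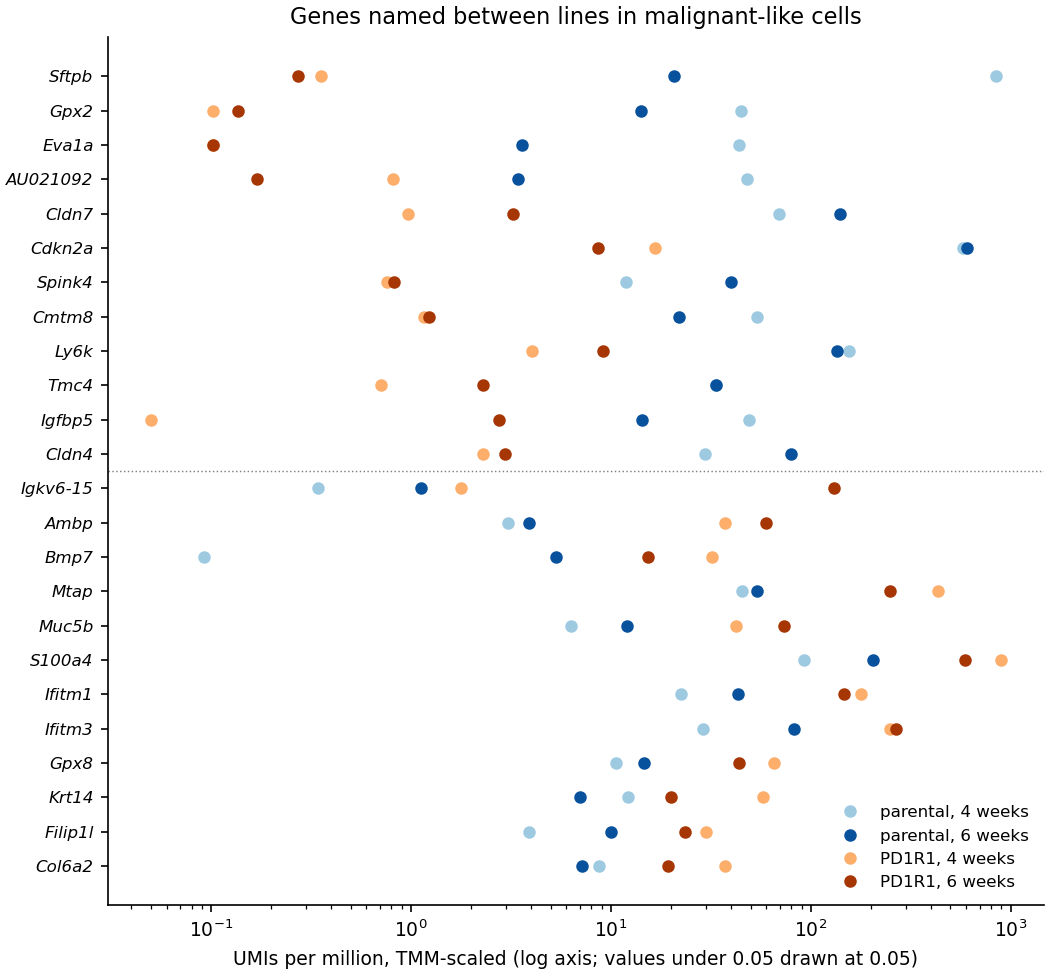
TMM-scaled CPM (log axis; values under 0.05 drawn at 0.05) of the 24 genes named by rule in malignant-like cells, 1 point per library. Cdkn2a lies at 16.6 and 8.64 in the PD1R1 libraries and at 575 and 607 in the parental ones.

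In the mm10 assembly, with GENCODE vM21 gene models, Cdkn2a (ENSMUSG00000044303) spans chromosome 4 from 89274471 to 89294653 on the minus strand. Mtap (ENSMUSG00000062937) lies at lower coordinates, from 89137122 to 89181081 on the plus strand, and Cdkn2b (ENSMUSG00000073802), which encodes the related inhibitor p15Ink4b, at higher ones, from 89306299 to 89311039 on the minus strand. All 3 are protein-coding. Cdkn2b was at 78.9 and 142 CPM in PD1R1 and 59.4 and 53.6 in parental malignant-like cells (log2 difference 0.97 ± 0.31, edgeR adjusted p 0.414). At least 1 Cdkn2a UMI was found in 6.17% and 11.98% of PD1R1 malignant-like cells and in 87.4% and 80.4% of parental ones, at median depths of 17884, 14296, 13300 and 14884 UMIs. In T or NK-like cells the shares were 1.79%, 5.13%, 14.2% and 7.25% at medians of 2448, 2753, 2457 and 2409. They are not a background of free RNA alone, since unscaled Cdkn2a in PD1R1 was at 22.01 and 74.3 CPM in their cluster c12 but at 0.94 and 0 in cluster c2. In B-like cells the shares were 0.216%, 0.171%, 0% (0 of 14 cells) and 0.902% at medians of 2370, 2812, 1355 and 2154. With every cell thinned to 1000 UMIs and shallower cells left out (10, 144, 65 and 185 malignant-like and 252, 131, 130 and 276 T or NK-like), the malignant-like shares were 1.02%, 1.15%, 39.4% and 38.7% and the T or NK-like shares 0.271%, 0.919%, 4.48% and 2.08%. The B-like shares thinned in this way were 0.0935% and 0% in PD1R1 (exact 95% upper bounds 0.520% and 0.319%, against lower bounds of 0.491% and 0.694% in malignant-like cells). In the PD1R1 4-week library 6 cells held 262 of the 326 Cdkn2a UMIs of malignant-like cells, against 19 of 253 at 6 weeks.

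**Figure D3:**
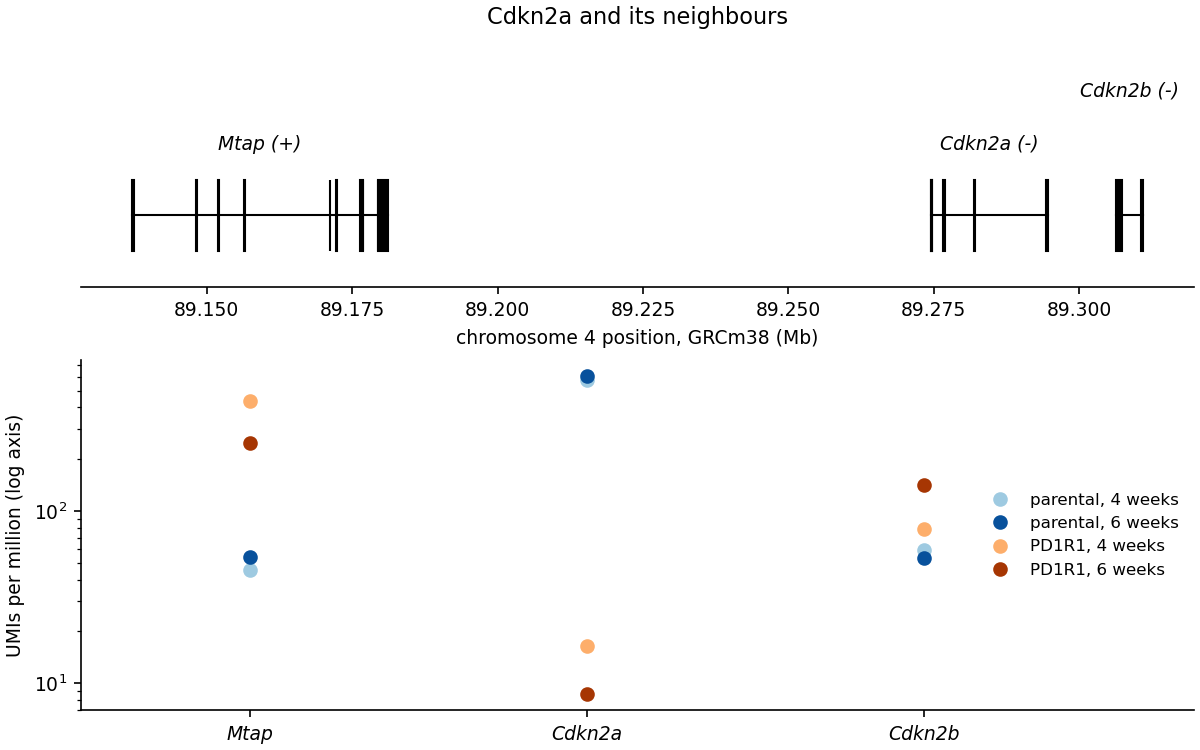
Gene models of Mtap, Cdkn2a and Cdkn2b on chromosome 4 (mm10 position in Mb) and their TMM-scaled CPM in malignant-like cells of each library. Cdkn2a is at 16.6 and 8.64 in PD1R1 against 575 and 607 in parental tumours, while Mtap is at 434 and 249 against 45.3 and 53.8.

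Cluster c5 was the malignant-like cluster with the most even numbers from the 4 libraries (471, 499, 557 and 541 cells), and a test within it was added after the data had been seen. There edgeR called 33 of 11685 genes, 6 higher and 27 lower in PD1R1. Cdkn2a fell by 6.27 ± 0.35 on the log2 scale (adjusted p 0.0073), Cldn7 by 5.61 ± 0.44 (0.011) and Ly6k by 4.42 ± 0.30 (0.0099). Cmtm8 fell by 3.79 ± 0.26 and Tmc4 by 4.21 ± 0.37. Among the genes that rose, Ambp increased by 4.53 ± 0.39 (adjusted p 0.011), the protease Cym by 3.26 ± 0.26, Filip1l by 2.16 ± 0.27, the water channel Aqp1 by 1.89 ± 0.22 and the troponin Tnnt2 by 1.39 ± 0.18. The remaining one was the claudin gene Cldn6, which is outside the naming rule and was chosen after its values were seen (5.04 ± 0.62, adjusted p 0.047).

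Of the 25 gene lists fixed for malignant-like cells, 8 passed camera, a test of a list against all other genes, at a preset correlation of 0.01, and 0 passed with an estimated correlation. That estimate was 0.67 for type I interferon, 0.59 for interferon-gamma and 0.27 for G2/M genes, far above the preset value. For the other passing lists it was -0.010 to 0.062. It was 0.0016 for epithelial genes, below the preset value, yet their unadjusted camera p rose from 8.7e-15 to 0.014. Camera with an estimated correlation also rests on the residual degrees of freedom, 2 here. The lost calls are thus not an effect of correlation alone. Epithelial genes fell as a group (adjusted p 2.2e-13, adjusted p = 0.34 with an estimated correlation), with 23 of 25 measured members lower and 12 passing when adjusted over the list alone. The transcription factor Ehf (-2.96 ± 0.16), occludin (Ocln, -2.80 ± 0.27), Cldn7 (-5.59 ± 0.70) and the adhesion molecule Epcam (-1.78 ± 0.23) led it. The list median was -1.22 at 4 weeks and -1.16 at 6 weeks. It was -0.73 and -0.80 with cells thinned to 1 depth, and -0.67 and -0.65 in cluster c5 alone. Of its genes, 16 of 26 also served to name malignant-like clusters. Over the 10 members not used for naming, 9 were lower, with a median of -1.11.

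Growth-signalling lists also moved. RAS and MAPK output genes fell (adjusted p 6.5e-05, adjusted p = 0.511 with an estimated correlation), 18 of 22 being lower and 2 passing when adjusted over the list alone, with the EGFR ligand Areg at -1.47 ± 0.19, the phosphatase Dusp5 at -0.78 ± 0.14 and the receptor Epha4 at -1.74 ± 0.46. YAP target genes fell (0.0030, adjusted p = 0.66 with an estimated correlation), 15 of 20 being lower and 2 passing when adjusted over the list alone. Its members Fjx1 (-2.07 ± 0.25), Ankrd1 (-0.72 ± 0.17) and Foxf2 (1.47 ± 0.25) went both ways, and its adjusted p was 0.078 without the PD1R1 6-week and 0.153 without the parental 4-week library. G2/M cell-cycle genes rose (9.2e-05, adjusted p = 0.689 with an estimated correlation), 23 of 25 being higher and 0 passing when adjusted over the list alone, with Top2a at 0.74 ± 0.14 and Cdk1 at 0.55 ± 0.15. The G1/S list passed at 0.041 (adjusted p = 0.66 with an estimated correlation; 19 of 24 higher, 0 when adjusted over the list alone), with the replication helicase subunits Mcm5 at 0.63 ± 0.15 and Mcm6 at 0.81 ± 0.27, but not without the PD1R1 4-week (0.088) or the parental 6-week library (0.365). Medians at 4 and 6 weeks were -0.41 and -0.27 for RAS and MAPK output, -0.38 and -0.24 for YAP targets, 0.55 and 0.07 for G2/M and 0.15 and 0.17 for G1/S genes.

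Immune-signalling lists were lower in PD1R1 malignant-like cells. Interferon-gamma response genes fell (adjusted p 2.1e-06, adjusted p = 0.717 with an estimated correlation), 23 of 24 being lower and 0 passing when adjusted over the list alone, with the adhesion ligand Icam1 at -1.19 ± 0.25 and the tryptophan-degrading enzyme Ido1 at -2.22 ± 0.60. Type I interferon genes fell (3.8e-04, adjusted p = 0.717 with an estimated correlation), 27 of 28 being lower and 0 passing when adjusted over the list alone. Both rested on the parental 4-week library: the list medians were -1.51 and -1.19 at 4 weeks and -0.08 and -0.03 at 6 weeks, and the adjusted p was 0.104 and 0.661 without that library. The Ifit3-led cluster c11 held 1.62%, 1.39%, 4.13% and 0.62% of malignant-like cells. Within c5 alone the interferon-gamma median was -0.78 at 4 weeks and 0.63 at 6 weeks, when 3 of 24 genes were lower, and the type I interferon median -0.85 and 0.32. Chemokines and cytokines fell (0.0030, adjusted p = 0.532 with an estimated correlation), 21 of 26 being lower and 4 passing when adjusted over the list alone. The neutrophil attractant Cxcl5 (-1.95 ± 0.42), Lif (-1.64 ± 0.30) and Il33 (-1.36 ± 0.28) were lower, whereas the monocyte attractant Ccl2 was higher (1.54 ± 0.20), and the list median was -0.19 at 4 and -0.86 at 6 weeks. That list did not pass without the PD1R1 6-week (0.068) or the parental 6-week library (0.097).

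**Figure D4:**
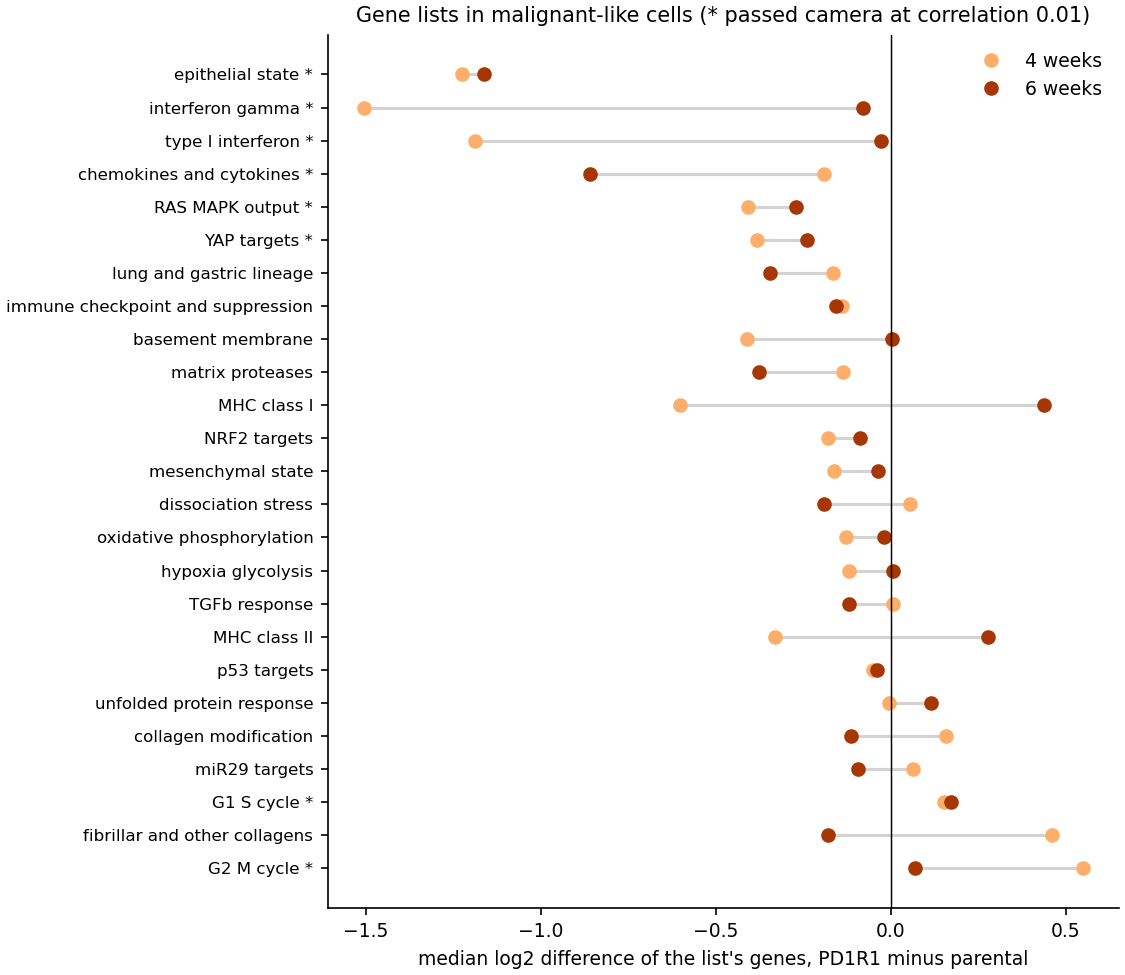
Median log2 difference, PD1R1 minus parental, of the measured members of each of the 25 lists in malignant-like cells, at 4 and at 6 weeks; an asterisk marks the 8 lists that passed camera at a preset correlation of 0.01. The epithelial list lies at -1.22 and -1.16, whereas the interferon-gamma list lies at -1.51 at 4 weeks and -0.08 at 6 weeks.

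The series title concerns loss of the miR-29a/b1 cluster, a microRNA locus whose targets include collagens and DNA-modifying enzymes. The feature list held 0 symbols beginning with Mir29, so the microRNA itself could not be read. Of 32 measured genes listed as miR-29 targets, 17 were higher and 15 lower in PD1R1 malignant-like cells, and the list did not pass camera (adjusted p 0.85). Its members with the smallest p were the cyclin Ccnd2 (-2.06 ± 0.22), the growth factor Igf1 (3.78 ± 0.71), the demethylation enzyme Tet1 (2.36 ± 0.57) and the kinase Cdk6 (-0.45 ± 0.15), and 1 member passed when adjusted over the list alone. The fry test for change in either direction gave an adjusted p of 0.041, and 4 other lists in these cells passed it, at 0.029 each for epithelial genes, chemokines and cytokines, p53 targets and RAS and MAPK output. Collagen chains did not pass (0.649; 7 of 10 higher), with Col6a2 at 1.82 ± 0.36 and Col6a1 at 1.22 ± 0.30. Collagen-modifying enzymes gave 0.786 (Plod2 0.86 ± 0.23, Loxl4 1.35 ± 0.48), basement membrane genes 0.126 (the laminin chain Lama3 -2.92 ± 0.40, Col4a5 -1.36 ± 0.33) and matrix proteases 0.245 (Adamts1 -1.40 ± 0.19). The collagen cross-linker Loxl2 (0.18 ± 0.27), Col1a1 (0.19 ± 0.87, at 0.34 to 1.63 CPM) and Col4a1 (-0.34 ± 0.25) differed by little more than their error or less. Several of these lists passed with a library left out. Collagen chains were higher without the PD1R1 6-week (6.9e-05) and the parental 4-week library (0.032), and collagen-modifying enzymes without the PD1R1 6-week library (0.0028). Basement membrane genes were lower without the PD1R1 4-week (0.017) and the parental 6-week library (0.0098), and matrix proteases without the PD1R1 4-week library (0.012).

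Further genes of interest in malignant-like cells differed by less than 1 log2 unit. The PD-1 ligand Cd274 was at -0.43 ± 0.18, the proliferation marker Mki67 at 0.29 ± 0.17, the mesenchymal regulator Zeb1 at 0.53 ± 0.21, E-cadherin (Cdh1) at -0.41 ± 0.18, Kras at 0.16 ± 0.19, Trp53 at 0.00 ± 0.23 and the MHC class I subunit B2m at -0.19 ± 0.30. The mesenchymal list gave an adjusted camera p of 0.963, with S100a4 at 2.32 ± 0.45 and Tnc at -1.57 ± 0.56. Lung and gastric lineage genes gave 0.571, with the lung lineage factor Nkx2-1 at -6.48 ± 1.19 and the surfactant gene Sftpd at -2.82 ± 0.81. Immune checkpoint genes gave 0.195 (Nectin2 -0.90 ± 0.20), p53 targets 0.731 (Btg2 -1.42 ± 0.17, Gdf15 -3.69 ± 0.52), MHC class I 0.919 and MHC class II 0.982. Lung and gastric lineage genes were lower without the parental 4-week library (0.035), and MHC class I genes higher without the PD1R1 4-week (0.044) and the parental 4-week library (0.021). NRF2 targets gave 0.215, hypoxia and glycolysis 0.308, oxidative phosphorylation 0.245, TGF-beta response 0.571, the unfolded protein response 0.85 and dissociation stress 0.85. The median, mean or direction of test differed in sign for miR-29 targets, mesenchymal genes, MHC class II genes and p53 targets in malignant-like cells, and for interferon-gamma genes in cluster c12 and MHC class I genes in plasmacytoid dendritic-like cells, of which none passed.

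Between 4 and 6 weeks, with line as a term, 0 of 14346 genes passed edgeR's test in malignant-like cells, so the genes with the widest gaps are given as values. On simulated data this test recovered 0.0% even of 16-fold changes, so the lack of calls does not show that genes stayed the same. The chitinase-like gene Chil4 went from 622 to 16.9 CPM in PD1R1 and from 797 to 64.9 in parental tumours (log2 difference -4.39 ± 0.50, 6 weeks minus 4 weeks). The water channel Aqp5 (-2.67 ± 0.29), the complement component C3 (-1.78 ± 0.16), the protease Htra1 (-1.99 ± 0.49) and the collagenase Mmp13 (-1.57 ± 0.53) were also lower at 6 weeks, Htra1 by -2.84 in PD1R1 and -1.17 in parental tumours and Mmp13 by -2.47 and -0.67. The antibody gene Ighg1 was at 1.68 and 85.1 in PD1R1 and 0 and 67.9 in parental tumours, with Igkc at 4.32 ± 1.0 and Jchain at 5.67 ± 1.23. Ighm (2.99 ± 1.79) was at 9.35 and 12.8 in PD1R1 and 0.69 and 45.5 in parental tumours. The neutrophil protein gene S100a9 stood at 0.76 and 11.3 in PD1R1 and 6.5 and 37.5 in parental tumours. Igkc and S100a9 are abundant in other cells of these libraries, where Igkc was at an unscaled 843, 973, 945 and 1045 CPM in B-like cells. Ighg1, Jchain and Igkc are also among the 10 leading genes of the unnamed cluster c8 (73, 22, 4 and 32 cells), which carries plasma-cell and B-cell genes. Whether transcripts of these cells account for the antibody genes in malignant-like cells was not tested. By edgeR 1746 genes were at an unadjusted p under 0.05, and DESeq2 called 202 (113 higher and 89 lower), among them Aqp5 (adjusted p 4.1e-14) and Chil4 (1.0e-06). In 5 simulated draws of this comparison DESeq2 called 786 of 70730 unchanged genes, more than the changed genes it called. Few genes were changed there by design, so this balance does not carry over to the 202. The 2 time points did not overlap for 5827 genes (40.6%, chance 33.3%).

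In T or NK-like cells, the neutrophil genes S100a9 and S100a8 were lower in PD1R1, with log2 differences of -4.37 ± 0.31 and -4.25 ± 0.38 (edgeR adjusted p 0.021 and 0.046, and 0.147 each with the time point as a block). S100a9 was at 2.28, 2.43, 57.2 and 42.1 CPM, while neutrophil-like cells of the same libraries held an unscaled 18499, 26367, 18209 and 29960 CPM of it and made up 2.39%, 6.80%, 21.8% and 18.5% of cells. Whether transcripts of neutrophil-like cells account for the difference was not tested, but they can enter the values of S100a9 and S100a8. These were the 2 genes called of 11447, with 409 at an unadjusted p under 0.05 and 21 called by DESeq2, and the count was 2 without the PD1R1 4-week library, both higher in PD1R1, 0 without the PD1R1 6-week library, 42 without the parental 4-week library and 1084 without the parental 6-week library. S100a9 and S100a8 thus lost their calls without the PD1R1 4-week (adjusted p 0.13 and 0.195) and the PD1R1 6-week library (0.16 each). The chemokine Cxcl2 (-2.98 ± 0.36), a leading gene of the neutrophil-like cluster c18, the granzyme Gzmg (-5.30 ± 1.17) and Calca (-3.37 ± 0.98) were lower and Tubb2a (1.48 ± 0.47), Pstpip2 (1.68 ± 0.77) and the receptor genes Trav7-1 (3.27 ± 0.57), Trav13-2 (3.08 ± 0.97) and Trbv3 (1.62 ± 0.57) higher without passing. Several of these differences lay mostly at 4 weeks: they were -4.58 at 4 and -0.55 at 6 weeks for Calca, 4.69 and 0.15 for Pstpip2, 4.61 and 0.52 for Trav13-2 and 2.09 and 0.50 for Tubb2a, but -5.21 and -3.28 for Gzmg, 1.02 and 2.76 for Trbv3 and 3.54 and 3.29 for Trav7-1. Cytotoxic effector genes fell (camera adjusted p 4.8e-12, adjusted p = 0.295 with an estimated correlation), all 14 being lower, with the granzymes Gzmc at -2.69 ± 0.70 and Gzmk at -1.51 ± 0.55 and the chemokine Ccl3 at -2.10 ± 0.56, and 2 passed when adjusted over the list alone. Ccl3 is also among the 10 leading genes of cluster c18. Naive and memory genes rose (2.3e-08, adjusted p = 0.295 with an estimated correlation), all 10 being higher, with the homing receptor Ccr7 at 0.96 ± 0.38 and Klf2 at 1.02 ± 0.43, 0 passing when adjusted over the list alone. Both lay mostly at 4 weeks, with medians of -2.24 at 4 and -0.23 at 6 weeks for cytotoxic and 2.30 and 0.17 for naive and memory genes. The composition of the class differed: cluster c2, led by naive genes such as Lef1 and Tcf7, held 50.1%, 52.4%, 4.22% and 37.7% of T or NK-like cells, and cluster c12, led by Cd8a and Pdcd1, held 9.31%, 13.4%, 64.0% and 10.8%.

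Regulatory T-cell genes also fell in T or NK-like cells (1.5e-05, adjusted p = 0.295 with an estimated correlation), 12 of 13 being lower, with Tnfrsf9 at -1.28 ± 0.50 and medians of -0.63 at 4 and -0.14 at 6 weeks. Exhaustion genes fell (0.0036, adjusted p = 0.295 with an estimated correlation), 12 of 16 being lower with Lag3 at -1.94 ± 0.70. Their median was -1.26 at 4 weeks and 0.05 at 6 weeks, and they gave 0.085 without the PD1R1 4-week and 0.684 without the parental 4-week library. Interferon-gamma genes rose (0.0063, adjusted p = 0.295 with an estimated correlation), 15 of 22 being higher, although Cxcl9 was at -3.83 ± 1.18, with medians of 0.31 and 0.15, and they did not pass without the PD1R1 4-week (0.085) or parental 6-week library (0.343). In each of these 3 lists 0 members passed when adjusted over the list alone. MHC class I genes gave 0.069, MHC class II genes 0.606 and type I interferon genes 0.26, and MHC class II genes were lower without the PD1R1 4-week library (0.0054).

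Because these clusters differ in weight between libraries, a test within c12 (161, 323, 455 and 300 cells) was added after the data had been seen. There 8 of 8686 genes passed edgeR's test (162 at an unadjusted p under 0.05, 6 by DESeq2), and Cxcl2 fell by 3.91 ± 0.39 (adjusted p 0.0035), as did S100a9 (-5.22 ± 0.66) and the inflammatory cytokine Il1b (-3.35 ± 0.49). These 3 genes are among the 10 leading genes of the neutrophil-like cluster c18, a class at 2.39%, 6.80%, 21.8% and 18.5% of cells, so its transcripts can enter their values in c12. Unscaled Cxcl2 was at 6.29, 4.31, 80.7 and 66.6 CPM in c12 and at 37364, 40832, 53995 and 46137 in neutrophil-like cells, and Il1b was at 6.29, 2.15, 33.5 and 34.9 in c12 and at 11033, 12404, 14675 and 13921 in neutrophil-like cells. The others were the receptor genes Trav7-1 (4.82 ± 0.67), Trav3-1 (3.78 ± 0.60; 2.25 at 4 and 5.44 at 6 weeks), Trbv3 (3.51 ± 0.51) and Trav12-3 (-5.37 ± 0.71), whose similar family members may share reads, and the transcript 5830405F06Rik (2.92). DESeq2 did not call Il1b (adjusted p 0.078), 5830405F06Rik (0.165) or Trav7-1 (0.99997). Left out in turn, the 4 libraries gave 28 to 66 called genes, the lowest without the parental 4-week and the highest without the PD1R1 6-week library. Trbv4, Trbv14 and the naive-state receptor Slamf6 (1.96 ± 0.52) did not pass. Cytotoxic effector genes fell within c12 as well (7.9e-05, adjusted p = 0.331 with an estimated correlation), 10 of 14 being lower with Ccl5 at -1.01 ± 0.60 and the c18 gene Ccl3 at -0.91 ± 0.32, though not without the PD1R1 6-week library (0.106). Naive and memory genes (0.0051, adjusted p = 0.504 with an estimated correlation) and MHC class II genes (0.026, adjusted p = 0.504 with an estimated correlation) rose, and both gave 0.379 without the PD1R1 4-week library. MHC class II genes gave 0.268 without the parental 6-week library. Type I interferon genes fell (0.0051, adjusted p = 0.331 with an estimated correlation), 13 of 17 being lower, and gave 0.098, 0.249, 0.050 and 0.073 without each library in turn, none of which passed. Exhaustion genes gave 0.404, MHC class I genes 0.404, interferon-gamma genes 0.741 and regulatory T-cell genes 0.713. Medians at 4 and 6 weeks were -0.46 and -0.64 for cytotoxic, 0.76 and 0.05 for naive and memory, 0.18 and 0.39 for MHC class II and -0.26 and -0.23 for type I interferon genes. Adjusted over the list alone, 1 naive and memory gene and 0 genes of the other 3 passing lists were called.

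Macrophage or monocyte-like cells of PD1R1 tumours held less of the chemokine Ccl24, at 115 and 194 CPM against 1289 and 762 in parental tumours (log2 difference -2.73 ± 0.37). The chitinase-like gene Chil3, a marker of alternative activation, was at 46.4 and 40.1 against 1044 and 164. By edgeR 0 of 10194 genes passed (407 at an unadjusted p under 0.05), and 6 by DESeq2, including Ccl24 (adjusted p 9.4e-12); edgeR called 5 genes without the PD1R1 6-week and 11 without the parental 6-week library. Rnase2a (-3.15 ± 0.67), Cstdc4 (-2.97 ± 1.14) and G0s2 (-2.86 ± 0.68) were lower, and Slc9b2 (2.54 ± 0.70), Tm4sf1 (1.57 ± 0.65) and the proliferation genes Rrm2 (2.06 ± 0.36), Hist1h1b (1.64 ± 0.47) and Spc24 (1.42 ± 0.37) higher. Of these, G0s2 is among the 10 leading genes of the neutrophil-like cluster c18, Tm4sf1 of the malignant-like clusters c5, c14 and c15 and Rrm2 of the T or NK-like cluster c19, so transcripts of other cells can enter their values. Tm4sf1 was at 3.35 at 4 and 0.11 at 6 weeks, Slc9b2 at 4.16 and 1.93 and Hist1h1b at 2.39 and 0.60. All 6 lists run in this class passed camera with lower values over the 4 libraries, each with adjusted p = 0.306 with an estimated correlation, but 3 of them were lower at 4 weeks alone. Medians at 4 and 6 weeks were -0.81 and 0.09 for interferon-gamma, -0.77 and 0.05 for type I interferon and -0.44 and 0.01 for MHC class I genes, against -0.79 and -0.67 for inflammatory, -0.73 and -0.34 for suppressive and -0.21 and -0.13 for MHC class II genes. Inflammatory genes fell (1.4e-07; all 13 lower), with Cxcl10 at -1.28 ± 0.36, Nos2 at -1.72 ± 0.51 and Il6 at -1.26 ± 0.43. Suppressive genes fell (4.3e-06; 17 of 19 lower), with Retnla at -2.43 ± 0.94 and the heme-degrading enzyme Hmox1 at -0.75 ± 0.26. Type I interferon (1.8e-05; 24 of 27 lower), interferon-gamma (1.8e-05; 20 of 22), MHC class I (1.0e-04; 19 of 20) and MHC class II genes (0.021; all 8) fell too. Without the parental 4-week library 1 list passed, that of inflammatory genes (0.0025), the others giving 0.153 for suppressive and for type I interferon genes, 0.519 for interferon-gamma, 0.315 for MHC class I and 0.421 for MHC class II genes. Without the PD1R1 4-week library MHC class I, MHC class II and type I interferon genes each gave 0.054, and MHC class II genes gave 0.168 without the PD1R1 6-week library. Adjusted over the list alone, 2 suppressive genes and 0 genes of the other lists passed.

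Neutrophil-like cells were few in PD1R1 (118 and 439 against 1119 and 1707), and 0 of 5281 genes passed edgeR's test, with 204 at an unadjusted p under 0.05 and 1 by DESeq2. The elastase inhibitor Serpinb1a was at 35.7 and 53.4 CPM against 6.49 and 5.75 (2.95 ± 0.42), and the scavenger receptor Cd36 at 0 and 6.36 against 46.8 and 45.0. Transcripts of other cell types separated the lines in this class: the B-cell gene Cd79a was at 296, 40.7, 1.95 and 24.0, and the keratin Krt18 at 20.4, 34.3, 196 and 51.4. Ube2c (3.57 ± 0.68), Mef2c (2.71 ± 0.99) and Ccr7 (2.70 ± 0.71) were higher, Krt7 (-2.42 ± 0.68) and the interferon-induced chemokine Cxcl10 (-2.24 ± 0.63) lower, and Tff1, with 0 UMIs in PD1R1 and 84 in parental cells, at least 5.61-fold lower over the line (1.06 to 8.86 with a library left out, the lowest without the PD1R1 6-week library). Mef2c was at 4.78 at 4 and 0.11 at 6 weeks, Ccr7 at 4.36 and 0.87, Ube2c at 0.68 and 4.09 and Cxcl10 at 0, 35.6, 155 and 84.9 CPM. Genes of suppressive neutrophils fell (0.0019, adjusted p = 0.331 with an estimated correlation), 14 of 15 being lower, but gave 0.077 without the parental 4-week library. MHC class II genes rose (0.0019, adjusted p = 0.331 with an estimated correlation), 4 of 5 being higher and 4 passing when adjusted over the list alone, with H2-Ab1 at 2.22 ± 0.63 and the invariant chain Cd74 at 2.33 ± 0.73. H2-Ab1 and Mef2c are among the 10 leading genes of the B-like clusters c0 and c1. The MHC class II list gave 0.237, 0.122 and 0.139 without the PD1R1 4-week, parental 4-week and parental 6-week libraries. Type I interferon (0.0055; 25 of 27 lower) and interferon-gamma genes (0.0090; 13 of 16 lower) fell, each with adjusted p = 0.66 with an estimated correlation, and gave 0.122 and 0.30 without the parental 4-week library. Type I interferon genes gave 0.109 without the PD1R1 4-week library. With the time point as a block interferon-gamma genes gave a camera adjusted p of 0.060. Medians at 4 and 6 weeks were -1.99 and 0.41 for type I interferon, -1.60 and 0.22 for interferon-gamma, -0.41 and -0.14 for suppressive and 3.08 and 0.45 for MHC class II genes. In the 3 lists that fell 0 members passed when adjusted over the list alone, and MHC class I genes gave 0.989, with a median below and a mean above 0, but were lower without the parental 6-week library (0.034). Leaving out the libraries in turn gave 13 genes without PD1R1 at 4 weeks, 24 without PD1R1 at 6 weeks, 27 without parental at 4 weeks and 45 without parental at 6 weeks.

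Dendritic-like cells (44, 91, 30 and 115) of PD1R1 tumours held less Inhba, an activin subunit (0 and 1.15 CPM against 91.0 and 17.6), and less of the lectin Mgl2 (11.2 and 2.31 against 157 and 35.2). Oasl1, an interferon-induced gene, was at -2.54 ± 0.48, Plet1 at -2.59 ± 0.60 and Wfdc13 at -3.06 ± 0.87, while Hspb1 (2.61 ± 0.69), Rbp1 (2.34 ± 0.61) and Arc (2.32 ± 0.79) were higher. The T-cell receptor gene Trbv17 had 40 UMIs in PD1R1 and 0 in parental cells, at least 12.7-fold higher (2.90 to 26.7 with a library left out, the lowest without the parental 6-week library), and Trbv3 was at 107, 45.0, 0 and 4.39. By edgeR 0 of 5846 genes passed (156 at an unadjusted p under 0.05, 0 by DESeq2), the counts being 20 without PD1R1 at 4 weeks, 44 without parental at 4 weeks and 205 without parental at 6 weeks. None of the 4 lists passed (MHC class I 0.254, MHC class II 0.254, type I interferon 0.154, interferon-gamma 0.317), and the type I interferon list had a median above 0 but a lower mean and test, and passed fry's test for change in either direction (0.0056). MHC class II genes were lower without the PD1R1 4-week library (0.018) and type I interferon genes without the parental 4-week library (0.010). In plasmacytoid dendritic-like cells (31, 77, 30 and 125), edgeR and DESeq2 each called 0 of 6136 genes (35 at an unadjusted p under 0.05 by edgeR), and edgeR called 35 without the parental 4-week library. The complement gene C4b was at 44.8, 78.6, 0 and 9.91 and Cxcl2 at 981, 339, 38.4 and 123, with Cxcl3 (2.54 ± 0.89), S100a9 (2.97 ± 0.81) and Nupr1 (2.38 ± 0.84) also higher. Cxcl2, Cxcl3 and S100a9 are leading genes of the neutrophil-like cluster c18. Cxcl3 was at 6.43 at 4 and 0.92 at 6 weeks, S100a9 at 4.70 and 1.29 and Nupr1 at 6.48 and 1.37. AA467197 (-2.60 ± 0.86), Pglyrp1 (-2.14 ± 0.60), Slc39a10 (-1.46 ± 0.80), Arl5b (-1.44 ± 0.53) and the sterol enzyme Cyp51 (-1.40 ± 0.63) were lower. Interferon-gamma genes fell (0.035, adjusted p = 0.958 with an estimated correlation), 8 of 9 being lower and 0 passing when adjusted over the list alone. Their median was 0.61 at 4 weeks and -0.58 at 6 weeks, and they gave 0.916 without the PD1R1 6-week and 0.678 without the parental 6-week library. MHC class I (0.921), MHC class II (0.279) and type I interferon genes (0.992) did not pass, and MHC class II genes were higher without the PD1R1 6-week (4.9e-04) and the parental 4-week library (0.024).

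**Figure D5:**
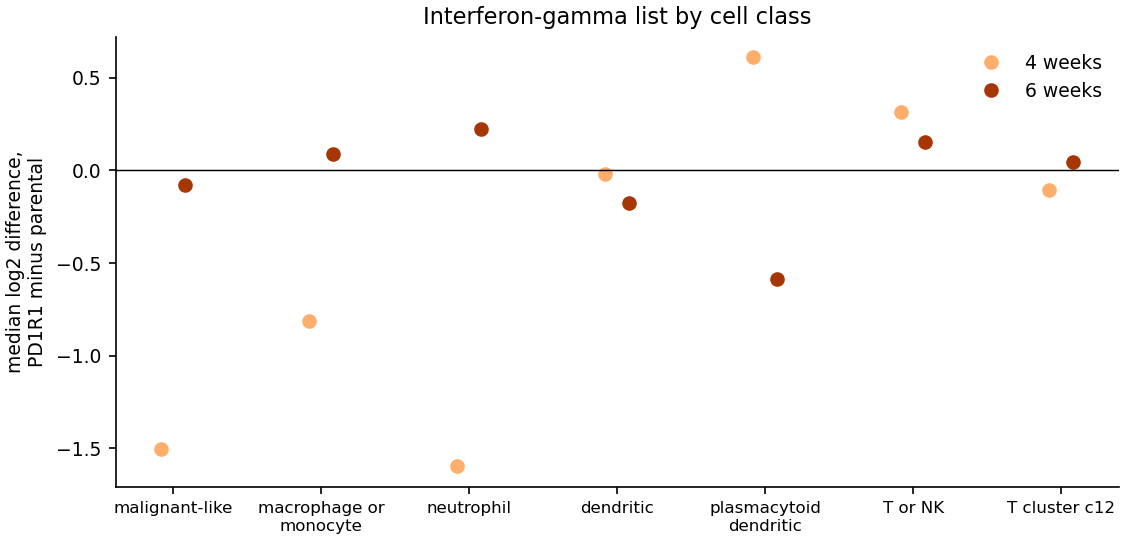
Median log2 difference, PD1R1 minus parental, of the interferon-gamma list in each cell class at 4 and at 6 weeks. Medians at 4 weeks were -1.51 in malignant-like, -1.60 in neutrophil-like and -0.81 in macrophage or monocyte-like cells, and 0.61 in plasmacytoid dendritic-like cells.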

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

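The tests below were chosen only after the result was seen, except those of loss or silencing of Cdkn2a alone and of B cells below the UMI minimum. Several results pointed in opposite directions at 4 and at 6 weeks, with a single library per line and time, and these differences between times were not tested. For log2 values they are those of at least 0.2 in size at both times. The malignant-like share of cells differed between lines by -33.2 percentage points at 4 weeks and 5.05 at 6 weeks. In malignant-like cells the median log2 difference of MHC class I genes was -0.60 at 4 weeks and 0.44 at 6 weeks, that of MHC class II genes -0.33 and 0.28, and that of B2m alone -0.72 and 0.24. In neutrophil-like cells type I interferon genes had medians of -1.99 and 0.41 and interferon-gamma genes -1.60 and 0.22. In plasmacytoid dendritic-like cells the interferon-gamma median was 0.61 at 4 weeks and -0.58 at 6 weeks. Cluster c26, led by Wfdc18, Lcn2 and Cldn4 and used in no comparison, held 12 cells of PD1R1 at 6 weeks and 25 of parental at 6 weeks, above the limit that a count of 0 allows.

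Cdkn2a was low in malignant-like cells of both PD1R1 libraries while its neighbour Mtap was high. RNA of other cells is argued against, since the log2 difference of Cdkn2a was -6.70 in malignant-like cells with no UMI of 7 genes of other cell types. So is a difference in depth, by the shares of cells with a Cdkn2a UMI at 1000 UMIs per cell. These were 1.02% and 1.15% in PD1R1 and 39.4% and 38.7% in parental malignant-like cells. The log2 difference was -5.38 with cells thinned to 5000 UMIs. That value cannot decide, since thinning keeps summed CPM on average, apart from the choice and weight of cells. Loss of every copy of a stretch that holds Cdkn2a and all of Mtap or Cdkn2b is also argued against, since the smaller of their log2 differences was 0.97. RNA levels cannot show whether a single copy was lost. The noncoding gene Gm12606, from 89235699 to 89273403 between Mtap and Cdkn2a, was not part of this test. Loss or silencing of Cdkn2a alone may account for the pattern and stays open: the level in PD1R1 malignant-like cells was 0.353 times that in T or NK-like cells of the same library at 6 weeks, but above it at 4 weeks, where 6 cells held 262 of 326 UMIs and the others were at 3.31 CPM, against 4.70 in T or NK-like cells without their 6 highest. This comparison cannot decide, because Cdkn2a in T or NK-like cells, high in their cluster c12, is not a background of free RNA alone. At equal depth the PD1R1 malignant-like shares were 1.02% and 1.15% against 0.0935% and 0% in B-like cells, apart by more than counting error at 6 weeks. In T or NK-like cells the PD1R1 shares were 0.271% and 0.919%. The Cdkn2a difference was -5.56 over all malignant-like cells and -6.70 in those with no UMI of other cell types, so part of the residue can come from other cells. Loss in part of the cells, silencing with residual expression and loss in all cells with such a residue cannot be told apart. The difference in origin between the lines is open and was not tested.

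Interferon genes were high in malignant-like cells of the parental 4-week library. RNA of other cells is argued against by the 4-week interferon-gamma median, which was -1.60 in cells with no UMI of 7 genes of other cell types. The median was -1.34 with cells thinned to 1 depth. That value cannot decide about depth, since thinning keeps summed CPM on average, apart from the choice and weight of cells. Cluster make-up stays open, since the 4-week median was -0.78 in malignant-like cluster c5, which holds similar numbers of cells from each library. Exposure shared by the whole tumour could reach every cell type and stays open: the 4-week median was -0.11 in T-cell cluster c12 and -0.02 in dendritic-like cells, but -0.81 in macrophage or monocyte-like and -1.60 in neutrophil-like cells. With 1 library per line and time, a state of that tumour and an effect of the line at 4 weeks are not separable here.

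B-like cells were nearly absent from the parental 4-week library. Doublet removal and clustering are argued against, since the share reached at most 0.288% over 5 settings, and B cells below the UMI minimum are too, since 2 of 14970 droplets with at least 100 but under 500 UMIs had at least 2 UMIs of Cd79a, Cd79b or Ms4a1. No setting loosened the gene or mitochondrial limit. In this library 478 and 575 droplets failed these limits and were not examined, so loss of B cells through them stays open. Lymphoid tissue in the other 3 libraries is a candidate explanation: the naive T-cell cluster c2 held 4.22% of T or NK-like cells in this library against 50.1%, 52.4% and 37.7% in the others, values that were known when the test was chosen. Lymphoid tissue and lymphocytes drawn into the tumour cannot be told apart from dissociated cells, and an effect of the line at 4 weeks was not tested.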

How the results depend on the processing

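Alternatives chosen after the data had been seen were cluster c5 alone, leaving out the low-UMI malignant-like cluster c13, limiting parental 4-week droplets to the number listed, T or NK clusters c12, c17 and c20, the epithelial list without naming genes, and leaving out libraries for shares and for lists outside malignant-like cells. Over 22 counts and shares, 96 alternative values lay within 1.5 times the reported count or within 1 SD between replicates of the reported share, and 70 moved further. Over 60 list tests, 274 values kept their call and direction, 64 lost the call, 17 gained it and 5 turned direction, and of 173 values that passed in neither fit 34 had the other direction. Over 283 named genes, 2519 values were the same, 414 gained a call, 12 lost it and 34 turned direction. Leaving out a library made a line rest on a single library assumed to vary like the other. For the weeks comparison this left 0 residual degrees of freedom and could not be fitted. The cause of the changes below was not tested.

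The count of genes called between lines in malignant-like cells was 0 by edgeR with TMM or RLE factors, with doublets kept, with the stricter filter, at resolution 2, with that number of droplets and without c13. It was 468 by DESeq2, 334 with no low-count filter, 80 in cells with no UMI of other cell types, 16 in cells thinned to 1 depth, 33 in c5 alone, and 0 to 510 with a library left out. Of 462 tested genes called by DESeq2, the other calls shared 324 of 332 with no filter, 75 of 80, 16 of 16 and 31 of 33, and 69 of 78 without the parental 4-week and 269 of 496 without the parental 6-week library. Between weeks DESeq2 called 202 and the fit with no filter 3. In T or NK-like cells the counts were 21 by DESeq2, 299 with no filter and 0 to 1084 with a library left out. With no filter the counts were 48 in dendritic-like, 179 in macrophage or monocyte-like, 55 in neutrophil-like and 24 in plasmacytoid dendritic-like cells, 61 in c12, 124 in c17 and 46 in c20. DESeq2 called 6 in macrophage or monocyte-like and 1 in neutrophil-like cells, 4 in c17 and 1 in c20, and RLE factors gave 2 in c20. By edgeR c17 and c20 gave 0 each, with 226 and 209 at an unadjusted p under 0.05. With a library left out the ranges were 0 to 205 in dendritic-like, 0 to 11 in macrophage or monocyte-like, 13 to 45 in neutrophil-like and 0 to 35 in plasmacytoid dendritic-like cells, 28 to 66 in c12, 0 to 517 in c17 and 2 to 25 in c20.

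With the time point as a replicate block the count was 0 in malignant-like cells, 0 in T or NK-like cells, 1 in neutrophil-like cells, 85 in c12 and 7 in c20, and 2 of 4 lists passed in dendritic-like cells. Samples share only this number, which is the time point: the 6-week minus 4-week differences of the lines correlated at 0.21 over 14346 genes, which are not independent, with only 2 pairs. Interferon-gamma genes in neutrophil-like cells gave an adjusted p of 0.06 with the block, and S100a9 and S100a8 in T or NK-like cells 0.147 each.

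With an estimated correlation 0 lists passed in T or NK-like, macrophage or monocyte-like, malignant-like, neutrophil-like and plasmacytoid dendritic-like cells and in c12. With a library left out 0 to 1 lists passed in dendritic-like, 1 to 6 in macrophage or monocyte-like, 0 to 4 in neutrophil-like and 0 to 2 in plasmacytoid dendritic-like cells and 1 to 3 in c12. Lists that turned direction had adjusted p ranges of 0.0212 to 0.0653 for MHC class I in malignant-like cells, 5.1e-10 to 0.122 for type I interferon and 2.1e-07 to 0.30 for interferon-gamma in neutrophil-like cells, and 2.9e-04 to 0.916 for interferon-gamma in plasmacytoid dendritic-like cells. The neutrophil-like share difference was -8.58 percentage points with the stricter filter and -12.0 with cells thinned to 1 depth before clustering. With a library left out the share differences were -29.3 to 1.14 for malignant-like, 6.08 to 22.4 for T or NK-like, 5.05 to 22.8 for B-like, -17.8 to -13.3 for neutrophil-like and -3.20 to -0.543 for macrophage or monocyte-like cells.

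Some genes turned direction, none of them called, and not all were near 0, with reported values of -1.39 for Pdcd1 and -1.63 for Irf8 in T or NK-like cells. In malignant-like cells Loxl2 was -0.019 thinned and -0.11 in c5, and -0.10 to 0.45 with a library left out. Col1a1 was -0.012 with the block and -1.28 to 0.94. Trp53 was -0.00011 with RLE factors, -0.0052 by DESeq2, -0.0091 with no filter, -0.00091 at resolution 2, -0.00084 without c13 and -0.073 in c5, and -0.22 to 0.27. H2-Aa was -0.052 in cells with no UMI of other cell types and Uhrf1 -0.14 thinned. With a library left out, Col4a1 ranged from -0.63 to 0.025, Kras from -0.022 to 0.37 and B2m from -0.64 to 0.17. In T or NK-like cells Pdcd1 ranged from -2.08 to 0.015, H2-DMb1 from -1.18 to 0.31, H2-Ab1 from -0.65 to 0.14 and Irf8 from -2.42 to 0.27. Ctss ranged from -0.71 to 0.15 in macrophage or monocyte-like cells and H2-Ab1 from -0.073 to 1.17 in plasmacytoid dendritic-like cells. In c12 the ranges were -0.83 to 0.17 for Entpd1, -0.079 to 0.75 for Ccr8, -0.47 to 1.0 for Ccr7, -0.40 to 1.27 for Erap1, -0.86 to 0.083 for H2-T23, -0.52 to 0.023 for H2-DMa and -0.0061 to 0.68 for H2-Ab1. The smaller classes held fewer UMIs: dendritic-like cells of the parental 4-week library held 279840 UMIs and plasmacytoid dendritic-like cells 154197, against 42143413 in malignant-like cells. The effect of depth in these classes was not tested.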

Other observations

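Genes of the Y chromosome separated the lines in malignant-like cells and were chosen after their values were seen. Ddx3y, Eif2s3y, Kdm5d and Uty, which are expressed widely in male cells, had 0 UMIs together in each PD1R1 library (50127934 UMIs over both) and 2390 and 849 UMIs in the parental libraries, or 56.7 and 23.8 CPM. Over the line, Eif2s3y was at least 336-fold lower in PD1R1 (1563 UMIs in parental cells), Ddx3y at least 237-fold (1104), Uty at least 62.7-fold (292) and Kdm5d at least 60.1-fold (280). With each library left out in turn these bounds were 130 to 457, 92.1 to 312, 24.4 to 92.0 and 23.4 to 86.8, the lowest without the PD1R1 6-week library. DESeq2 called Eif2s3y (adjusted p 9.3e-11) and Ddx3y (7.1e-10), and edgeR did not (0.158 and 0.157). In c5, a cluster tested after the data were seen, edgeR gave adjusted p-values of 0.011 for each. In T or NK-like cells the 4 genes had 2, 2, 11 and 19 UMIs, or 0.342, 0.215, 4.27 and 1.93 CPM.

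Xist, which silences an X chromosome in female cells, was at 370, 465, 440 and 560 CPM in T or NK-like cells and at 188, 287, 216 and 354 in macrophage or monocyte-like cells. Malignant-like cells held 15.5, 27.2, 7.76 and 40.9. Fibroblast-like cells, at 220, 248, 254 and 266, had 0 UMIs of the 4 Y-linked genes in every library.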
